A study of Mus musculus with 4 samples.

How the data were processed

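Live single cells carrying CD45, a surface protein of leukocytes, were sorted from pituitary glands of male C57BL/6N mice, and 1 droplet library was made at each of 4 ages: newborn, 1-week, 3-week and 8-week. The labels name whole pituitaries or separate anterior and posterior parts, without saying which went into which library, and do not give the number of animals pooled. Per the labels' protocols, glands were digested with collagenase and DNase, dead cells were excluded by dye, and libraries were made with a 10x Genomics Chromium 3′ kit. Per the submitters' processing notes, Cell Ranger 7.1.0 and the mm10 genome build were used. The deposited matrices hold whole-number counts of molecules (UMIs, unique molecular identifiers) per gene and barcode, with no normalization by the authors, per the file headers and the values. Whether reads on introns were counted is not given in the sources used here. The barcodes are those the authors deposited, and each has at least 500 UMIs.

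The libraries held 368, 1981, 4767 and 6840 barcodes at newborn, 1-week, 3-week and 8-week, with 4704104, 13607976, 43912505 and 69455826 UMIs over the same 32285 genes. Barcodes with at least 200 genes and under 10% mitochondrial UMIs were kept. Scrublet doublet scores were computed within each library with scanpy 1.11.5, and the highest were removed at 0.8% per 1000 barcodes, which took out 1, 31, 176 and 366 barcodes. This left 357, 1914, 4446 and 6326 cells. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were chosen without mitochondrial, ribosomal, haemoglobin, hormone, immunoglobulin or T cell receptor genes, and cells of all libraries were clustered together on 30 principal components with 15 neighbours (Leiden, resolution 1, igraph 0.11.9), without integration. Clusters were called X-like from markers fixed before the data were examined. A name needed at least 3 raised markers, and clusters with markers of unrelated classes were called mixed. The scoring thresholds of this naming were set on the data, and conventional and plasmacytoid dendritic cells were pooled after the clusters were seen. In the main clustering no cluster was named plasmacytoid, so dendritic cell-like cells there were those of cluster 5, named conventional. Mixed or unnamed clusters of at least 40 cells were split once more.

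For each class and library, raw counts were summed and scaled to a common total in the usual way, as CPM. With 1 library per age there is no replicate and no test of age: ratios carry exact conditional 95% Poisson intervals and shares exact (Clopper-Pearson) 95% binomial intervals, and both cover counting error only. Beside a share of 0 stands the limit that 3 counts of the total would give. A gene at 0 counts was set at a floor of 3 counts. A list member counted as measured at 10 CPM or more in either library, and as higher or lower, in size only, at 2-fold or more with an interval excluding 1. The median log2 ratio of each of 26 lists fixed before the data were examined is given relative to the median of all measured genes, which was 0.083 from newborn to 8-week, -0.17 from newborn to 1-week, 0.20 from 1-week to 3-week and 0.048 from 3-week to 8-week. Its interval comes from 200 Poisson draws of the counts. Its percentile among 10000 random lists of the same size matched on mean expression describes these libraries only. After the data were seen, random lists were also matched on genomic span, the distance between gene ends in GENCODE vM21, which is of the same genome build. Loci are from that annotation. Values against these lists are relative to the median of random lists matched on expression and span, not to that of all measured genes. They thus differ from the other list medians in more than span.

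Genes were named by a rule fixed before the data were examined: from newborn to 8-week, the 12 with the highest lower bound and the 12 with the lowest upper bound of the CPM ratio, 5 each way for each step between neighbouring ages, and from each list the 4 measured members with the largest ratio in either direction or those needed to describe a count. Left out were genes under 10 CPM in both libraries, mitochondrial, ribosomal, haemoglobin, immunoglobulin, T cell receptor, predicted and sex-linked marker genes, genes of the lists of other cells' RNA, and genes whose macrophage-like CPM was less than 1 part in 5 of that in another named class of at least 20 cells in the same library. That last filter was applied if it held in either library. To compare shares of cells with a UMI, each cell was thinned to 1000 UMIs and shallower cells were left out. The calculation of intervals and list percentiles was tested on Poisson counts simulated at the pooled expression of the newborn and 8-week libraries. Over 8434 genes with 200 genes changed 4-fold, the interval held the true ratio for 95.8% of genes, and 0.036% of unchanged genes passed the size rule. The intervals assume this same Poisson model, so the test says nothing of spread between cells or animals.

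Alternatives covered the cell filter, doublets, clustering, scaling between libraries (including TMM from edgeR 4.0.16 in R 4.3.3), weight of cells, pseudocount, CPM minimum, thinning depth, cycling cells and the ranking of genes. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.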

Results

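Single-cell RNA sequencing was carried out on live cells carrying CD45, a surface protein of leukocytes, that were sorted from pituitary glands of male C57BL/6N mice. There was 1 library at each of 4 ages, newborn, 1-week, 3-week and 8-week, and so no replicate at any age. The libraries held 4704104, 13607976, 43912505 and 69455826 UMIs (counted RNA molecules) in 368, 1981, 4767 and 6840 barcodes, in that order. Median UMIs per barcode were 11891, 5753, 6962 and 8470, and 357, 1914, 4446 and 6326 cells were retained. The comparisons ask which immune cells the gland held at each age and how gene expression of its macrophages differed from newborn to 8-week and between neighbouring ages. Intervals are exact 95% intervals that cover counting error within a library, not differences between animals.

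Macrophages, phagocytes that reside in the tissue, were the largest class at newborn, 1-week and 8-week, and B cells were at 3-week. Macrophage-like cells made up 42.3% (interval 37.1 to 47.6) of retained cells at newborn, 40.8% (interval 38.6 to 43.0) at 1-week, 24.0% (interval 22.8 to 25.3) at 3-week and 36.7% (interval 35.5 to 37.9) at 8-week. Among cells of the named immune classes alone, their share was 46.9%, 41.9%, 26.0% and 38.5%. B cell-like cells were 13.4% at newborn, 22.8% at 1-week, 35.1% (interval 33.7 to 36.5) at 3-week and 16.5% at 8-week. T cell-like cells were 0.840% (interval 0.174 to 2.44) at newborn, from 3 cells, and 15% (interval 14.1 to 15.9) at 8-week. Natural killer (NK) cell-like cells were 2.24%, 1.62%, 7.96% and 11.6% at the 4 ages. Monocyte-like cells, which resemble the blood cells that enter tissues and can become macrophages, were 14.6% (interval 11.1 to 18.7) at newborn, 12.9% at 1-week, 3.80% at 3-week and 4.33% (interval 3.84 to 4.86) at 8-week. Dendritic cell-like cells were 2.80%, 2.40%, 2.38% and 2.56%. With the newborn library clustered on its own no cluster was named T, NK or dendritic cell-like (0% for each), and the dendritic cell-like share was 1.36% at 1-week and 3.94% at 8-week.

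Smaller classes included granulocytes and innate lymphocytes. Neutrophil-like barcodes, short-lived granulocytes, were 6.44% at newborn, 4.75% at 1-week, 0.765% at 3-week and 2.29% at 8-week. Haematopoietic progenitor-like barcodes were 2.52%, 2.25%, 3.08% and 5.64%. Of these, 2, 8, 10 and 7 were in the dividing cluster 14.2, whose 10 top genes held 1 progenitor marker, Prtn3, and 1 dendritic cell marker, Cd209a, so that its name is doubtful. With the newborn library clustered on its own the progenitor-like share there was 0%. At 3-week and 8-week both classes held shallow barcodes, with medians of 578.5 and 620 UMIs for neutrophil-like and 601 and 660 UMIs for progenitor-like ones. Without barcodes under 1500 UMIs the neutrophil-like shares there were 0.0717% and 0.283%, and the progenitor-like shares 0.191% and 0.0708%. Of the 34 neutrophil-like barcodes at 3-week, 32 were in cluster 24, and all 32 were also in the 8-week library. Of the 127 3-week barcodes in progenitor-like cluster 19, 83.5% were in the 8-week library too. Whether these barcodes are cells of the 3-week gland was not tested. Basophil-like cells were 0.840%, 1.25%, 0.270% and 0.206%, mast cell-like cells 1.40%, 1.15%, 0.0675% and 0.0948%, and gamma-delta T or innate lymphoid cell-like cells 2.80%, 1.25%, 0.382% and 0.316%. Pituitary endocrine-like cells, the hormone makers that the CD45 gate should exclude, were 9.80%, 2.56%, 1.55% and 1.04%. Of these, 30 of 69 barcodes at 3-week were also in the 8-week library, and 27 of 66 at 8-week in the 3-week library. Without barcodes under 1500 UMIs the endocrine-like shares were 3.15%, 0.490%, 0.239% and 0.301%, and with each library clustered on its own 6.16%, 0%, 0% and 0.316%. That clustering also gave 0%, 1.25%, 0% and 0% for basophil-like, 0%, 1.15%, 0.337% and 0.253% for mast cell-like and 6.44%, 1.31%, 0% and 0.332% for gamma-delta T or innate lymphoid cell-like cells. Clusters with markers of unrelated classes held 0 of 357 cells at newborn, which allows a share of up to 0.840%, and 0.0522%, 5.85% and 3.67% at the later ages. With each library clustered on its own the newborn share was 5.88%. The CD45 gate, the calling of barcodes and the depth of a class all bear on these shares.

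**Figure D1:**
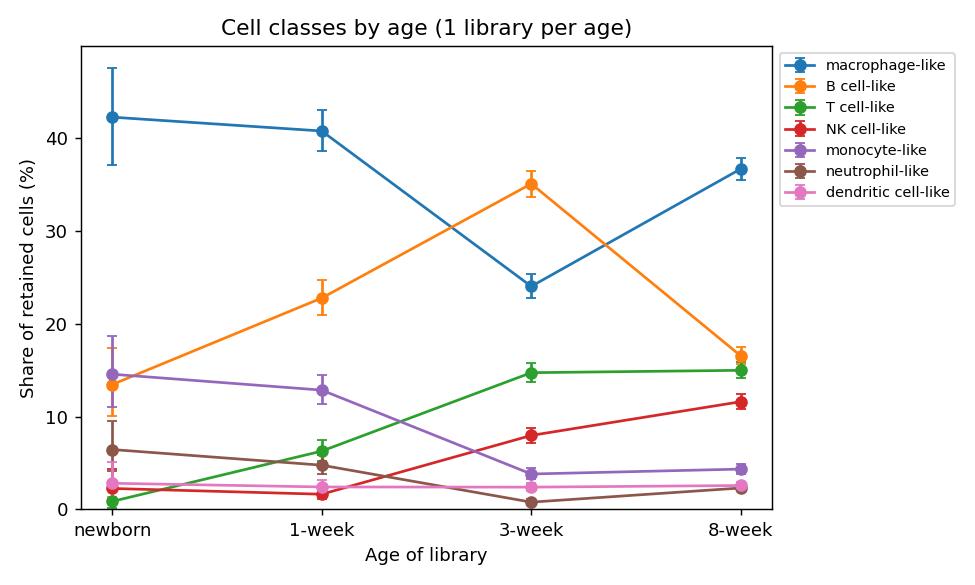
Share of retained cells, in percent, by age for 7 immune classes, with exact 95% binomial intervals as bars and 1 library per age. The macrophage-like share was lowest at 3-week (24.0%), where the B cell-like share was highest (35.1%), and the monocyte-like share was lower at 3-week and 8-week than at newborn and 1-week.

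MHC class II molecules display peptides to helper T cells, and their transcription depends on the transactivator Ciita. In macrophage-like cells these genes were low at newborn and high at 8-week. The list median was 5.41 (interval 5.2 to 5.52) on the log2 scale relative to all measured genes, at percentile 100 among random lists matched on expression, a description of these libraries only. All 7 measured members were at least 2-fold higher at 8-week. H2-Ab1 (chromosome 17, 34257689 to 34269419, mm10), the beta chain of the I-A molecule, was 47.2-fold (interval 41.8 to 53.4) higher, at 122 CPM at newborn and 5762 CPM at 8-week. Its alpha chain H2-Aa (chromosome 17, 34282744 to 34287823) was 45.0-fold (interval 39.6 to 51.2) higher, and H2-Eb1, of the I-E molecule, 49.9-fold (interval 43.9 to 57.0) higher. Cd74, the invariant chain that guides these molecules, stood at 561 and 15151 CPM. Ciita had 2 UMIs at newborn and was 114-fold (interval 31.6 to 944) higher at 8-week. The newborn UMIs of H2-Aa came from 4 of 151 cells, and its log2 ratio, 5.49, was 4.45 with each library clustered on its own and 7.72 without barcodes under 1500 UMIs. For H2-Ab1, at 5.56, these values were 4.48 and 7.15. MHC class I genes, which present peptides to killer T cells, had a median of 0.38, at percentile 85.7, and 2 of 11 members were 2-fold higher. That median was 0.89 without a CPM minimum and 1.0 against random lists matched on genomic span as well.

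Macrophages at tissue borders and around vessels carry a set of scavenging and adhesion genes, among them Lyve1, a hyaluronan receptor, and Pf4, a chemokine. In macrophage-like cells these genes were lower at 8-week than at newborn. The list median was -2.71 (interval -2.91 to -2.47), at percentile 0, and 10 of 14 members were at least 2-fold lower. Lyve1 (chromosome 7, 110850607 to 110863239) stood at 176 CPM at newborn, 192 at 1-week, 9.52 at 3-week and 0.418 at 8-week, from 10 UMIs there, and was 419.9-fold (interval 226 to 883) lower at 8-week than at newborn. The coagulation factor gene F13a1 was 24.6-fold (interval 21.9 to 27.7) lower, Pf4 18.4-fold (interval 17.3 to 19.5) lower and Timd4, a receptor for dying cells, 18.1-fold (interval 9.92 to 34.0) lower. The exception was Ms4a7, a membrane protein of macrophages, which was 2.47-fold (interval 2.35 to 2.59) higher. Macrophage-like cells came from different clusters at the younger and older ages. Clusters 3, 1 and 6 held 41.7%, 23.8% and 17.9% of them at newborn and 33.9%, 38.9% and 12.8% at 1-week. At 3-week, clusters 7, 8, 4 and 6 held 39.0%, 23.6%, 19.7% and 9.35%. Their shares at 8-week were 35.3%, 27.6%, 19.3% and 12.1%. Of the barcodes in cluster 6, 36 of 100 at 3-week were also in the 8-week library, and 65 of 281 at 8-week in the 3-week library. Its median depths were 926.5 and 2612 UMIs at these ages. Whether such barcodes are macrophages of the gland was not tested.

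**Figure D2:**
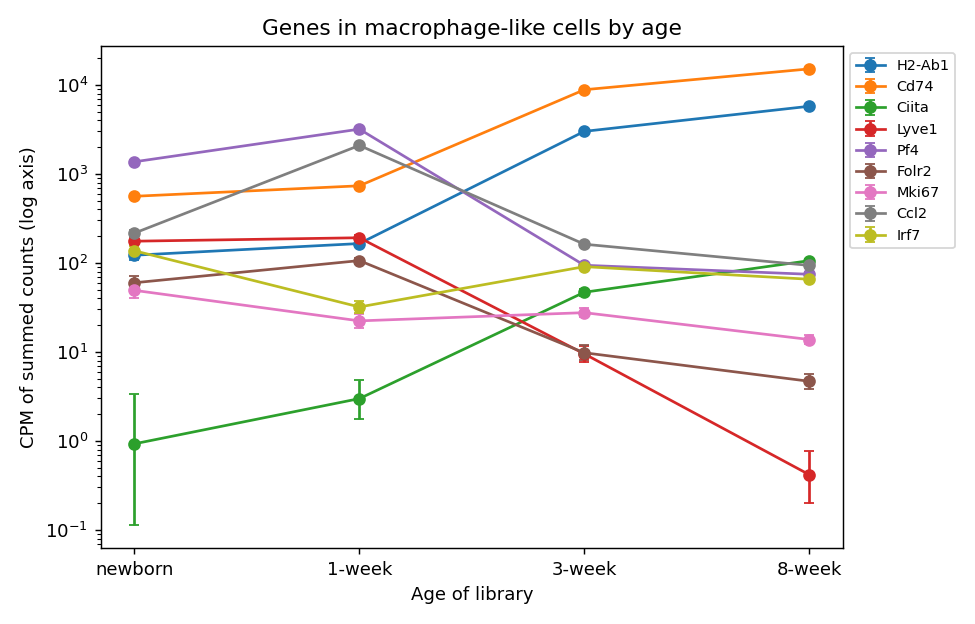
CPM of summed macrophage-like counts by age, on a log axis, for 9 genes, with exact 95% Poisson intervals as bars and 1 library per age. H2-Ab1 was at 122, 165, 3009 and 5762 CPM, and Pf4 at 1369.9, 3189, 94.2 and 74.6 CPM.

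Dividing cells express cell cycle genes, and growing cells need glycolysis and oxidative phosphorylation to make energy and building blocks. All 3 sets were lower in macrophage-like cells at 8-week than at newborn. For cell cycle genes the median was -2.25 (interval -2.47 to -2.13), at percentile 0, and 16 of 18 members were at least 2-fold lower, with Rrm2, a subunit of ribonucleotide reductase, 23.1-fold (interval 14.1 to 38.9) lower and Birc5 15.6-fold (interval 12.1 to 20.3) lower. Without cells that had a UMI of 5 cycling genes the median was -1.14, and with each library clustered on its own -4.70. Glycolysis genes had a median of -1.17 (interval -1.28 to -1.11), at percentile 0.02, and 7 of 11 were 2-fold lower, such as Gapdh at 901 and 289.6 CPM. Oxidative phosphorylation genes had a median of -1.10 (interval -1.17 to -1.02), at percentile 0.01, and 8 of 15 were 2-fold lower, such as the ATP synthase gene Atp5g3 at 203 and 58.8 CPM. Without a CPM minimum the glycolysis and oxidative phosphorylation medians were -0.66 and -0.59. Their genes span little of the genome, and ratios differed with genomic span in the 3 classes examined. With measured genes in 3 equal groups by span, the median log2 ratio in macrophage-like cells was -0.43 in the shortest group and 0.60 in the longest. The same medians were -0.26 and 0.52 in monocyte-like cells and -0.49 and 0.43 in B cell-like cells. From 1-week to 3-week they were -0.30 and 0.69 in macrophage-like cells, against -0.13 and -0.17 from newborn to 1-week and -0.0042 and 0.084 from 3-week to 8-week. Ribosomal genes took 16.1%, 15.9%, 9.32% and 8.02% of macrophage-like UMIs, so the 2 younger and the 2 older libraries stood apart on these measures, which cannot be separated from age. Against random lists matched on span as well, the oxidative phosphorylation list lay -0.41 from their median, at percentile 1.65, and the glycolysis list at percentile 0.06.

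**Figure D3:**
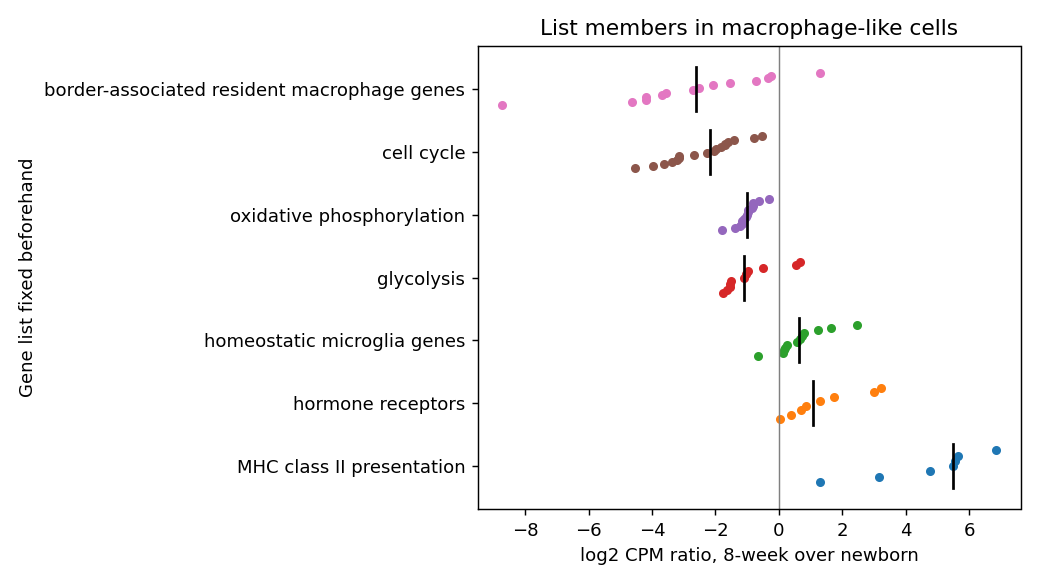
Log2 ratio of CPM, 8-week over newborn, in macrophage-like cells for the measured members of 7 gene lists, with 1 point per gene and the list median as a black bar. MHC class II genes lay above 0 and most border-associated and cell cycle genes below it.

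**Figure D4:**
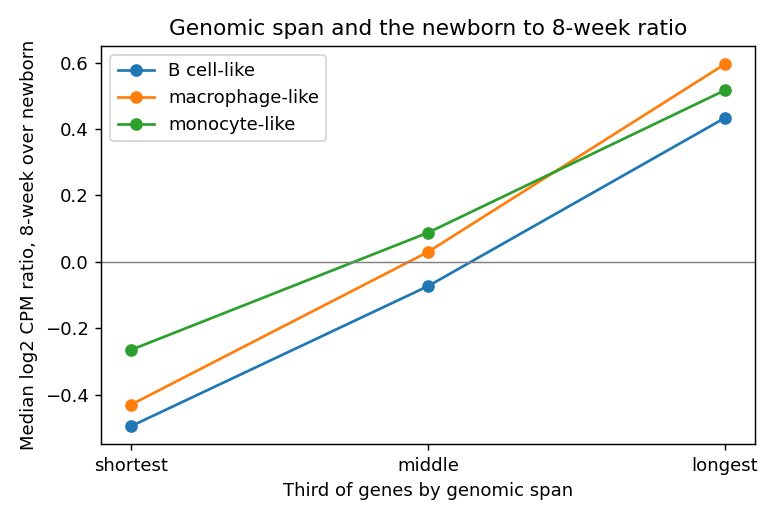
Median log2 ratio of CPM, 8-week over newborn, for measured genes in 3 equal groups by genomic span, in B cell-, macrophage- and monocyte-like cells. In all 3 classes the median was below 0 in the shortest group and above 0 in the longest.

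Microglia, the macrophages of the brain, share a homeostatic gene set with other resident macrophages. Its median in macrophage-like cells was 0.54, at percentile 92.7, and 3 of 12 members were 2-fold higher, such as the transcription factor Sall1 at 4.65 and 25.8 CPM, while the median was 1.09 without a CPM minimum. Nuclear receptors for thyroid hormone and steroids let cells respond to hormones. The hormone receptor list had a median of 1.0 (interval 0.76 to 1.39), at percentile 99.7, and 4 of 8 measured members were at least 2-fold higher. Among them the mineralocorticoid receptor Nr3c2 stood at 6.97 and 55.9 CPM and the glucocorticoid receptor Nr3c1 at 85.0 and 211 CPM. That median was 0.63 without a CPM minimum and 0.37 with span-matched lists, at percentile 89.8. Monocyte-derived cell genes, such as the calcium-binding S100a4 and the chemokine receptor Ccr2, had a median of -0.91, at percentile 0.695. S100a4 was 24.5-fold (interval 20.9 to 28.7) lower and Ccr2 2.22-fold (interval 1.68 to 2.99) higher, and the median was 0.17 without a CPM minimum, the opposite sign, and -0.51 with span-matched lists.

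Immune effector genes had members in both directions from newborn to 8-week. Interferon response genes, induced by viruses, had a median of 0.39, at percentile 89.5, with 2 higher and 2 lower of 12. That median was 0.90 against span-matched lists, at percentile 99.98, 0.95 without a CPM minimum and 0.20 by the mean of per-cell CPM. Inflammatory cytokines and chemokines had a median of -0.43, at percentile 12.5, with 3 higher and 5 lower of 13. The cytokine Il1b was 4.0-fold (interval 3.78 to 4.24) higher. Immediate-early and dissociation genes, which tissue digestion can induce, had a median of 0.15, at percentile 74.4, and 4 of 16 were higher. Medians were -0.20 for complement, -0.12 for lysosome, -0.35 for lipid handling and -0.33 for scavenger and efferocytosis receptors, at percentiles 37, 54.9, 22.5 and 17.8. Against span-matched lists the scavenger list lay -0.67 from their median, at percentile 0.57. Medians of purinergic signalling, growth factors and macrophage transcription factors were 0.57, 0.046 and 0.36, at percentiles 83.5, 54.3 and 89.4. The purinergic median was 0.20 with a minimum of 50 CPM and 0.26 after thinning. The transcription factor median was 0.011 with each library clustered on its own and 0.11 after thinning. Without a CPM minimum the medians of inflammatory, complement, lysosome, lipid handling and scavenger genes and growth factors had the opposite sign, at 0.094, 0.35, 0.39, 0.043, 0.11 and -0.29. Against span-matched lists the inflammatory, complement, lysosome and immediate-early lists lay 0.28, 0.18, 0.10 and 0.81 from their median. The growth factor median was 0.67 without cycling cells and -0.18 after thinning, and thinning moved the lipid handling median to -0.15. Fetal and imprinted growth genes had 2 measured members, with a median of -2.09. Osteopontin, Spp1, which acts in tissue remodelling, stood at 499 and 6.57 CPM, and the mannose receptor Mrc1 at 573 and 198 CPM. The ectonucleotidase Entpd1 stood at 84.5 and 348 CPM.

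Among single genes of all kinds, those named here were among those with the strongest bounds on their ratio from newborn to 8-week. Mmp12 (chromosome 9, 7344381 to 7369499), the macrophage metalloelastase, had 3 newborn UMIs and 7192 at 8-week, 216-fold (interval 73.8 to 1047) higher, and the collagenase Mmp13 had 1 newborn UMI and was 101-fold (interval 18.1 to 4000.3) higher. Hspa1b, a heat shock protein whose reads are hard to tell from those of its near-identical neighbour Hspa1a, was 65.4-fold (interval 36.5 to 131) higher. Cxcl9, a chemokine induced by interferon gamma, had 0 newborn UMIs and was at least 38.9-fold higher. Also higher were Ch25h, which makes an oxysterol, 31.7-fold, the membrane protein gene Ptchd1 25.9-fold, and Myo1e, a myosin, 15.1-fold. Pdgfc, a growth factor with 2 newborn UMIs, was 37.5-fold (interval 10.3 to 309.8) higher, and the channel gene Kcnj9, with 1, 49.3-fold (interval 8.82 to 1952) higher. Apoc1 (chromosome 7, 19689481 to 19692660), an apolipoprotein, was 31.9-fold (interval 27.0 to 37.8) lower at 8-week. Folr2, a folate receptor, was 12.8-fold lower, the haemoglobin scavenger Cd163 11.7-fold, and the lectins Cd209f, Colec12 and Clec4n 22.2-fold, 9.97-fold and 5.79-fold lower. Ehd1, Rgs7bp, Ms4a4a, Nt5dc2 and Cbr2 were 7.47-fold, 8.85-fold, 7.37-fold, 6.87-fold and 6.56-fold lower. Alternatives moved the ratio of 19 of the 24 genes that the naming rule chose by over 1.5 times and left the other 5, Pf4, Ehd1, Ms4a4a, Nt5dc2 and Clec4n, within that. Low-count genes moved most, since a pseudocount and the smaller total of thinned cells both limit a ratio. Log2 ratios were 7.75 for Mmp12, 6.66 for Mmp13, 5.28 for Cxcl9 and 5.62 for Kcnj9, and after thinning to 1000 UMIs per cell they were 3.91, 1.10, 1.08 and 0.17. For Cd209f, at -4.47, thinning gave -1.08, and for Folr2, at -3.68, the mean of per-cell CPM gave -2.52. With the filter on genes of other classes applied only in the library where a gene was higher, 6 of the 24 names were shared.

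RNA typical of other cell types was found in macrophage-like cells, and how it came there was not tested. Haemoglobin RNA was close to absent in macrophage-like cells of the younger libraries, with Hbb-bs at 0, 0.352, 640.1 and 251 CPM. It was uneven between classes at 8-week, with Hbb-bs at 928 CPM in NK cell-like, 7.32 in B cell-like, 1.80 in monocyte-like and 1.70 in T cell-like cells. The erythroid list median was 5.61, and 1.77 after thinning, with 0 newborn UMIs of all 4 measured genes, set at the floor of 3 counts. Its 8-week level depended on which cells were included, since Hba-a1 had 2009 UMIs at 8-week, 13 without cells that had a UMI of the cycling genes and 15 without barcodes under 1500 UMIs. No direction can be read from counts that low. In the last setting cells were clustered anew, so deeper barcodes could leave the class too. After thinning to 1000 UMIs per cell, Hbb-bs and Hba-a1 had 545 and 180 UMIs at 8-week. So few could come from very few barcodes, whose number was not counted, and the erythroid medians may not describe macrophage-like cells at large. Growth hormone RNA, Gh, was at 142, 81.1, 361 and 322 CPM, and the corticotroph gene Pomc at 109.6, 149, 10.3 and 16.5 CPM. The hormone and granule list had 2 members higher and 2 lower of 4, with a median of -0.47, or 0.80 without cycling cells. The B cell RNA median was 0.15 (3 measured), and alternatives moved it both ways, to -1.31 without barcodes under 1500 UMIs, 1.80 by the mean of per-cell CPM, 1.69 without cycling cells, 1.26 with doublets kept and 1.13 without a CPM minimum. Medians were 3.83 for T and NK cell RNA (Gzma and Nkg7 alone), 1.24 for neutrophil RNA (Csf3r alone) and -0.59 for mesenchymal and endothelial RNA (Pecam1 alone). In macrophage-like cells mast cell RNA was highest at newborn, with Cma1 at 39.5, 0.528, 0.732 and 0.711 CPM, Mcpt4 at 28.8, 0.352, 0.366 and 0.0418 CPM and Tpsb2 at 20.4, 0, 0.275 and 0.167 CPM, so every comparison with newborn includes that difference.

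The first week after birth brings exposure to microbes and milk, and the newborn to 1-week comparison covers it. Part of the inflammatory list was 2-fold higher at 1-week in macrophage-like cells, and most antiviral genes were 2-fold lower. Inflammatory genes had a median of 1.20 (interval 1.05 to 1.30), at percentile 100, and 7 of 14 members were 2-fold higher, among them the chemokines Ccl7, Ccl2 and Cxcl1 but not Ccl3, Ccl4, Ccl12 or Cxcl2. RNA typical of other classes was higher in the same step, with medians of 1.97 for neutrophil RNA (3 measured), 1.61 for B cell RNA (4 measured) and 4.49 for T and NK cell RNA (Cd3g and Cd3d alone). Ccl24, an eosinophil attractant, was 16.1-fold (interval 13.2 to 19.8) higher, Ccl7 10.6-fold (interval 9.14 to 12.4) and Ccl2 9.67-fold (interval 8.81 to 10.6). Tnfsf18, a ligand of the tumour necrosis factor family with 0 newborn UMIs, was at least 12-fold higher, and Mmp12 33.1-fold (interval 11.2 to 161) higher. Immediate-early and dissociation genes had a median of 1.01, at percentile 100, with 4 of 16 at 2-fold, and border-associated genes 0.94, at percentile 100, with Mrc1 among the higher ones. Interferon response genes had a median of -1.11 (interval -1.28 to -0.94), at percentile 0, and 9 of 12 were 2-fold lower. The interferon regulator Irf7 was 4.28-fold (interval 3.55 to 5.18) lower, Oasl2 3.94-fold, complement factor Cfb 5.60-fold, the steroid-responsive Fkbp5 4.79-fold and the phosphatase Acp5 4.34-fold. By the mean of per-cell CPM the log2 ratio of Acp5, -2.12, was -0.94, and that of Mmp12, 5.05, was 5.85. Cell cycle and glycolysis genes had medians of -0.78 and -0.50, and growth factors and transcription factors 0.67 and 0.46. MHC class II genes had a median of 0.58, or 0.93 by the mean of per-cell CPM, with 0 of 6 at 2-fold. That mean also gave 0.44 for growth factors and -0.59, in place of -0.19, for monocyte-derived cell genes.

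Between 1-week and 3-week mice near weaning, and most of the newborn to 8-week difference in MHC class II and border-associated genes lay in this step. The younger and older libraries also stood apart here. In macrophage-like cells the median log2 ratio was -0.30 in the shortest group of genes by span and 0.69 in the longest. Ribosomal genes took 15.9% of UMIs at 1-week and 9.32% at 3-week. A difference between these libraries thus cannot be separated from age. Against span-matched lists MHC class II and border-associated genes lay 3.98 and -2.75 from the median of those lists. MHC class II genes had a median of 3.58 (interval 3.28 to 3.70), at percentile 100, with 7 of 8 members 2-fold higher at 3-week. Border-associated genes had a median of -2.80 (interval -2.90 to -2.71), at percentile 0, with 12 of 14 members 2-fold lower. Pf4 was 33.9-fold (interval 31.8 to 36.1) lower, Spp1 55.7-fold (interval 48.0 to 64.9), Ccl24 59.2-fold (interval 50.002 to 70.6), and the lectin Cd209g, with 1 UMI at 3-week, 308-fold (interval 54.4 to 12222) lower. Tnfsf18 had 0 UMIs at 3-week and was at least 60.9-fold lower. Interferon response genes had a median of 1.68 (interval 1.48 to 1.83), at percentile 100, with 10 of 12 higher. Hspa1b was 31.5-fold (interval 24.8 to 40.7) higher, Ch25h 23.1-fold, Gpr31b, with 3 UMIs at 1-week, 38.3-fold (interval 12.9 to 187), Frmpd4 13-fold and Myo1e 11.7-fold. Oxidative phosphorylation, monocyte-derived, lipid handling, scavenger and cell cycle genes had medians of -1.04, -1.08, -0.91, -0.83 and -0.63. Against span-matched lists they lay -0.48, -0.79, -0.81, -1.13 and -0.45 from the median of those lists. By the mean of per-cell CPM the monocyte-derived median was -0.017, and the log2 ratio of Spp1, -5.80, was -4.39. RNA typical of other classes differed in the same step, with medians of 8.16 for erythroid RNA (4 of 4 higher), -3.13 for neutrophil RNA (2 of 3 lower), 0.56 for B cell RNA and -0.57 for T and NK cell RNA. By the mean of per-cell CPM these were 7.85, -2.32, 1.07 and 0.89.

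Between 3-week and 8-week mice reach sexual maturity, and medians of MHC class II, border-associated and interferon genes lay nearer 0 than in the step before. MHC class II genes had a median of 0.79 (interval 0.78 to 0.83), at percentile 100, and 1 of 8 members, Ciita, at 2-fold. Cell cycle genes had a median of -0.89, at percentile 0, with 5 of 15 lower. Inflammatory, interferon and border-associated genes had medians of -0.54, -0.38 and -0.23, while lipid handling, scavenger and hormone receptor genes had 0.18, 0.20 and 0.31. By the mean of per-cell CPM the border-associated and interferon medians were -0.10 and -0.23. RNA typical of other classes differed in the same step, with medians of -1.87 for B cell RNA (4 of 5 lower) and -1.32 for erythroid RNA (3 of 4 lower), or -1.0 and -1.08 by the mean of per-cell CPM. The integrin gene Itgb8, which activates transforming growth factor beta, was 10.3-fold (interval 7.5 to 14.5) higher, and Mmp12 5.15-fold (interval 4.75 to 5.59) higher. The receptor gene Gabbr2 was 8.86-fold higher, H2-M2 3.88-fold and Pdgfc 3.02-fold. Cbr2 was 2.91-fold (interval 2.30 to 3.70) lower, Ehd1 2.46-fold, St18 2.32-fold, the cytokine Il1a 1.85-fold and Tgif2 2.20-fold. By the mean of per-cell CPM the log2 ratio of Gabbr2, 3.15, was 1.99 and that of Cbr2, -1.54, was -0.55.

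The share of macrophage-like cells with a UMI of a marker shows how widely a gene is detected. Of 26 markers after thinning to 1000 UMIs per cell, H2-Aa, Cd74 and Il1b had a higher share at 8-week than at newborn, with intervals apart. Lyve1, Mrc1, Cd163, Folr2, Spp1 and Pf4 had a lower one, and the other 17 had overlapping intervals. H2-Aa was detected in 2.68% (interval 0.736 to 6.73) of cells at newborn, 3.76% (interval 2.53 to 5.36) at 1-week, 48.7% (interval 45.5 to 51.8) at 3-week and 66.7% (interval 64.7 to 68.6) at 8-week, and without thinning in 2.65%, 6.79%, 74.5% and 82.1%. In T cell-like cells, which should lack it, the thinned shares were 0% of 3 cells, 0.840%, 5.37% and 7.76%, and those without thinning 0%, 2.5%, 28.5% and 37.4%. Lyve1 was detected in 4.70% (interval 1.91 to 9.44) at newborn, 9.73% (interval 7.73 to 12) at 1-week, 0.397% (interval 0.108 to 1.01) at 3-week and 0 of 2208 cells at 8-week, which allows a share of up to 0.136% with a UMI at that depth. Without thinning its shares were 11.3%, 19.97%, 0.748% and 0.258%, against 0%, 0%, 0.128% and 0% in B cell-like cells, where the thinned shares were all 0%. Il1b was detected in 22.8% (interval 16.3 to 30.4) at newborn and 49.5% (interval 47.4 to 51.6) at 8-week, or 43.7% and 71.8% without thinning, against 0% and 2.12% of B cell-like cells after thinning and 0% and 12.6% without. P2ry12, a purinergic receptor of resident macrophages, was detected in 18.8%, 17.8%, 16.5% and 17.9% after thinning and 74.8%, 58.9%, 57.5% and 55.4% before, against 0% and 0.0962% after and 2.08% and 1.34% before at newborn and 8-week in B cell-like cells. Ccr2 was detected in 2.68% (interval 0.736 to 6.73) at newborn and 3.26% (interval 2.56 to 4.09) at 8-week (6.62% and 11% without thinning), against 0% and 0.0962% of B cell-like cells (0% and 0.765% without thinning). The division marker Mki67 was detected in 0.671% (interval 0.0170 to 3.68) and 0.453% (interval 0.217 to 0.831), or 11.9% and 2.54% without thinning. In B cell-like cells these shares were 0% and 0.385% after thinning and 0% and 1.15% without. At 1-week the thinned shares were 1.56% in macrophage-like and 3.02% in B cell-like cells, so B cell-like cells do not lack this gene. Median depths were 13267, 6782, 9718 and 9781 UMIs in macrophage-like, 8948, 5818.5, 7724 and 8542 in T cell-like and 6044.5, 3889, 5347 and 5859.5 in B cell-like cells. Macrophage-like cells too shallow to thin, 2, 10, 62 and 115 by age, were left out.

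**Figure D5:**
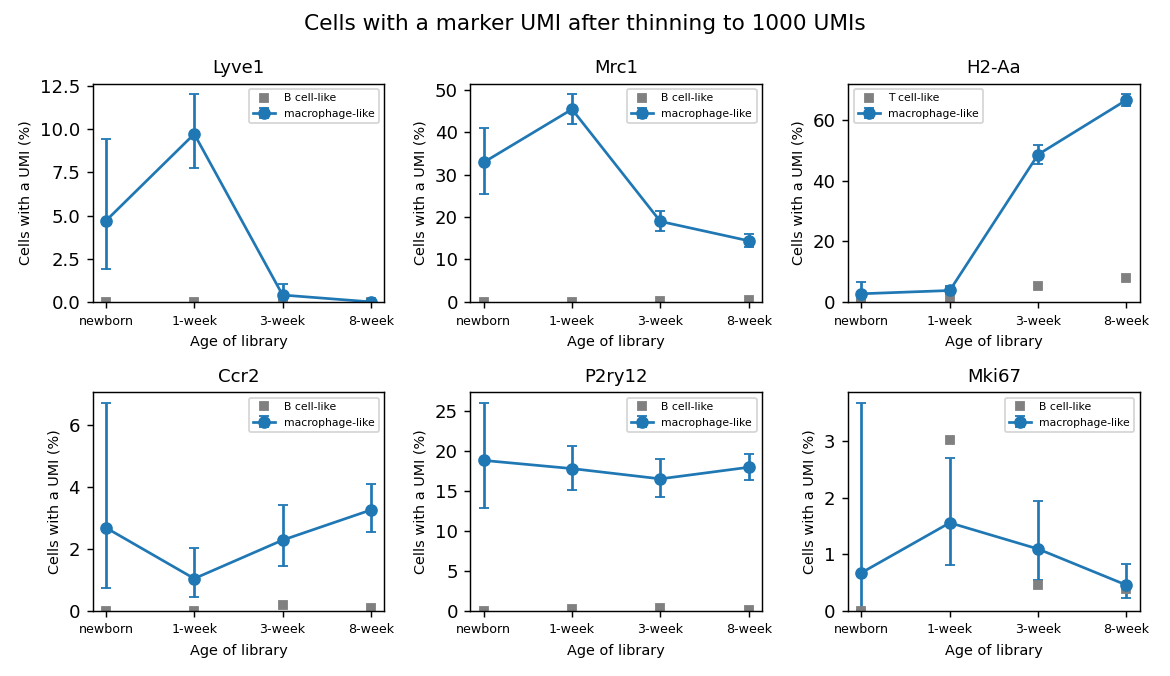
Share of macrophage-like cells, in percent, with a UMI of 6 markers after thinning to 1000 UMIs per cell, by age, with exact 95% binomial intervals as bars. Grey points are a class that should lack the gene, except for Mki67, which B cell-like cells do not lack. H2-Aa was at 2.68% at newborn and 66.7% at 8-week.

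Pairs of markers show whether the same macrophage-like cells carried both genes. Cells with H2-Aa less often had P2ry12, with odds ratios of 0.343 (interval 0.232 to 0.50) at 3-week and 0.284 (interval 0.225 to 0.357) at 8-week. They more often had Ccr2, with odds ratios of 11.5 (interval 2.79 to 102) and 37.2 (interval 6.44 to 1494). Cells with Cx3cr1, the fractalkine receptor, less often had H2-Aa, at 0.648 (interval 0.497 to 0.844) and 0.583 (interval 0.482 to 0.704), and more often P2ry12, at 1.97 (interval 1.34 to 2.95) and 1.78 (interval 1.40 to 2.27). The 3-week value for Cx3cr1 with P2ry12 was 3.06 at a depth of 2000 UMIs. Lyve1 and Folr2 were found together, at 46.9 (interval 4.24 to 713) at newborn and 8.30 (interval 4.23 to 16.1) at 1-week. At 1-week, Lyve1 with Cx3cr1 had an odds ratio of 0.467 (interval 0.276 to 0.780), or 0.237 at 2000 UMIs. Mrc1 with H2-Aa had odds ratios of 0.240 (interval 0.0708 to 0.651) at 1-week, 0.592 (interval 0.422 to 0.827) at 3-week and 1.34 (interval 1.02 to 1.76) at 8-week. At 2000 UMIs these were 0.221, 0.853 and 1.10, so the last 2 lay nearer 1.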

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

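The tests of chance coincidence of barcodes and of independent progenitor-like cells were chosen after the result was seen. Before the same-droplet test, correlated profiles of shared barcodes had been seen, though not the measure tested.

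The 3-week and 8-week libraries shared 364 barcodes, which drew attention as a signal that no comparison used. Chance at the rate of the other library pairs would give 21, and the count was 17.4 times that. Independent progenitor-like cells are argued against for the 3-week library, since 83.5% of the 127 barcodes in the shallow progenitor-like cluster 19 at 3-week were also in the 8-week library (interval 75.8 to 89.5). Of the 350 8-week barcodes in that cluster, 36% were in the 3-week library (interval 31.0 to 41.3). The argument does not reach the other 8-week barcodes. In 98.0% of 196 pairs with UMI counts at least 5-fold apart (interval 94.9 to 99.4), the lower copy had more of its UMIs on genes of its own higher copy than on those of the median other copy. In these pairs molecules of the same droplets may thus have been counted in both libraries. The other shared barcodes were not covered by this test, and many were shallow in both libraries, such as a pair with 588 and 889 UMIs. How the shared barcodes arose was not tested. The lower copies of all 364 pairs had a median of 623.5 UMIs, with 217 in the 3-week and 147 in the 8-week library.

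Clusters with markers of unrelated classes held 493 barcodes, 0, 1, 260 and 232 by age, which stood out because they belonged to no single class. Their median depth was 21402.5 UMIs at 3-week and 22965.5 at 8-week, against 6948 and 8344.5 for retained cells. Their median doublet scores were 0.0921 and 0.139, against 0.0244 and 0.0237. In mixed cluster 26.6, 15 of 28 barcodes at 3-week were also in the 8-week library. In the other mixed clusters with at least 20 barcodes at 3-week, 0% to 22.6% were. Whether the mixed barcodes are droplets with more than 1 cell was not tested.

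Border-associated genes went opposite ways in a pair of classes from newborn to 8-week. The relative median was -2.71 in macrophage-like and 0.76 in monocyte-like cells, a difference of -3.47, and this difference was not tested. The monocyte-like values rest on 52 newborn cells.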

How the results depend on the processing

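Alternatives chosen after seeing the data were those without lower copies of shared barcodes, without barcodes under 1500 UMIs, with the filter on genes of other classes applied only in the library where the gene is higher, with random lists matched on span and with 10 other seeds for clusters made without list genes. Values stayed within their interval in 314 of 416 comparisons of class shares, 329 of 485 of list medians, 1743 of 2215 of single genes, 144 of 312 of marker shares and 25 of 31 of marker pairs, and within 1.5 times in 13 of 18 of counts. The sign changed 1 time among list medians beyond percentile 2.5 at either end of random lists and 30 times among those between, over 18 medians. It changed 20 times among single genes at 2-fold or more with an interval excluding 1. In 12 of these a count of 0 stood at the floor of 3 and 2 more were under 10 CPM in both libraries, so 14 show no direction and 6 are left. No paired analysis was possible because each age had 1 library, so differences between animals are unknown. Another scaling between libraries shifts a list and all measured genes alike, so it is no test of a list median unless genes cross the CPM minimum. The erythroid list had no value from newborn to 8-week with each library clustered on its own, cycling cells left out or barcodes under 1500 UMIs left out, since no member was measured. The median log2 ratio of all measured genes was 0.083 from newborn to 8-week, -0.070 with totals without mitochondrial, ribosomal, haemoglobin and hormone genes, -0.43 without a CPM minimum and -0.031 after thinning. It was -0.17 from newborn to 1-week (0.0077 with TMM) and 0.20 from 1-week to 3-week (0.082 with TMM), and list medians are relative to it. Depth limits the newborn library most, where 357 cells leave genes under about 10 CPM with few UMIs. For every value that follows, the cause was not tested, except that leaving out cells or barcodes removes them by construction and a pseudocount, thinning or another CPM minimum acts on low counts by construction.

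Newborn shares with each library clustered on its own were NK 0% (from 2.24%), T 0% (from 0.840%), basophil 0% (from 0.840%), dendritic 0% (from 2.80%), gamma-delta T or innate lymphoid 6.44% (from 2.80%), progenitor 0% (from 2.52%), mast 0% (from 1.40%), mixed 5.88% (from 0%) and endocrine 6.16% (from 9.80%). 1-week shares with each library clustered on its own were dendritic 1.36% (from 2.40%), progenitor 0.679% (from 2.25%), mixed 2.14% (from 0.0522%) and endocrine 0% (from 2.56%). 3-week shares with each library clustered on its own were NK 9.60% (from 7.96%), T 13.3% (from 14.7%), basophil 0% (from 0.270%), gamma-delta T or innate lymphoid 0% (from 0.382%), mast 0.337% (from 0.0675%), neutrophil 0% (from 0.765%) and endocrine 0% (from 1.55%). 8-week shares with each library clustered on its own were NK 12.9% (from 11.6%), basophil 0% (from 0.206%), dendritic 3.94% (from 2.56%), macrophage 35.4% (from 36.7%), mast 0.253% (from 0.0948%), mixed 2.97% (from 3.67%) and endocrine 0.316% (from 1.04%). Medians with each library clustered on its own from newborn to 8-week were MHC class II 4.32 (from 5.41), monocyte-derived -1.12 (from -0.91), cell cycle -4.70 (from -2.25), immediate-early 0.20 (from 0.15) and transcription factors 0.011 (from 0.36). Newborn to 8-week log2 ratios at the floor or under 10 CPM, of opposite sign but no direction, with each library clustered on its own were Hba-a1 -1.12 (from 5.91), Hba-a2 -1.33 (from 5.46) and Hbb-bt -0.86 (from 5.39). Newborn shares with at least 500 genes and under 5% mitochondrial UMIs were progenitor 0.601% (from 2.52%), mixed 3.90% (from 0%) and endocrine 3.0% (from 9.80%). 1-week shares with at least 500 genes and under 5% mitochondrial UMIs were progenitor 0.60% (from 2.25%), mixed 1.47% (from 0.0522%) and endocrine 1.36% (from 2.56%). 3-week shares with at least 500 genes and under 5% mitochondrial UMIs were B 29.6% (from 35.1%), NK 9.06% (from 7.96%), T 16.8% (from 14.7%), dendritic 2.96% (from 2.38%), progenitor 0.222% (from 3.08%), macrophage 26.6% (from 24.0%), mixed 9.0% (from 5.85%), neutrophil 0.138% (from 0.765%) and endocrine 0.443% (from 1.55%). 8-week shares with at least 500 genes and under 5% mitochondrial UMIs were NK 12.7% (from 11.6%), T 17.3% (from 15%), progenitor 0.144% (from 5.64%), macrophage 38.3% (from 36.7%), mixed 5.97% (from 3.67%), monocyte 4.96% (from 4.33%), neutrophil 0.559% (from 2.29%) and endocrine 0.379% (from 1.04%). Newborn shares with doublets kept were progenitor 1.12% (from 2.52%). 1-week shares with doublets kept were progenitor 1.44% (from 2.25%) and mixed 0.308% (from 0.0522%). 3-week shares with doublets kept were mixed 8.50% (from 5.85%). 8-week shares with doublets kept were mixed 6.58% (from 3.67%) and monocyte 4.90% (from 4.33%). Medians with doublets kept from newborn to 8-week were MHC class II 5.06 (from 5.41), cell cycle -2.63 (from -2.25) and B cell RNA 1.26 (from 0.15). Newborn shares with resolution 0.5 were progenitor 0.840% (from 2.52%). 1-week shares with resolution 0.5 were progenitor 1.15% (from 2.25%). 3-week shares with resolution 0.5 were NK 8.84% (from 7.96%) and progenitor 2.32% (from 3.08%). 8-week shares with resolution 0.5 were NK 13% (from 11.6%), T 13.7% (from 15%) and progenitor 4.32% (from 5.64%).

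Newborn shares with the lower copies of shared barcodes left out were progenitor 0.843% (from 2.52%). 1-week shares with the lower copies of shared barcodes left out were progenitor 1.10% (from 2.25%). 3-week shares with the lower copies of shared barcodes left out were B 36.8% (from 35.1%), NK 9.84% (from 7.96%), progenitor 0.425% (from 3.08%), neutrophil 0.0708% (from 0.765%) and endocrine 1.13% (from 1.55%). 8-week shares with the lower copies of shared barcodes left out were NK 13.8% (from 11.6%) and T 13.4% (from 15%). Medians with the lower copies of shared barcodes left out from newborn to 8-week were MHC class II 7.06 (from 5.41) and immediate-early 0.22 (from 0.15). Newborn shares with barcodes under 1500 UMIs left out were progenitor 0.287% (from 2.52%), mixed 4.01% (from 0%) and endocrine 3.15% (from 9.80%). 1-week shares with barcodes under 1500 UMIs left out were progenitor 0.981% (from 2.25%), macrophage 43.2% (from 40.8%), mixed 1.20% (from 0.0522%) and endocrine 0.490% (from 2.56%). 3-week shares with barcodes under 1500 UMIs left out were B 37.3% (from 35.1%), progenitor 0.191% (from 3.08%), mixed 7.51% (from 5.85%), neutrophil 0.0717% (from 0.765%) and endocrine 0.239% (from 1.55%). 8-week shares with barcodes under 1500 UMIs left out were B 18.3% (from 16.5%), NK 12.8% (from 11.6%), T 16.9% (from 15%), dendritic 2.99% (from 2.56%), progenitor 0.0708% (from 5.64%), macrophage 38.6% (from 36.7%), mixed 4.55% (from 3.67%), neutrophil 0.283% (from 2.29%) and endocrine 0.301% (from 1.04%). Medians with barcodes under 1500 UMIs left out from newborn to 8-week were MHC class II 7.06 (from 5.41), immediate-early 0.23 (from 0.15) and B cell RNA -1.31 (from 0.15). Newborn to 8-week log2 ratios of opposite sign with barcodes under 1500 UMIs left out were Ebf1 -0.47 (from 1.36). Newborn to 8-week log2 ratios at the floor or under 10 CPM, of opposite sign but no direction, with barcodes under 1500 UMIs left out were Hba-a1 -1.08 (from 5.91), Hba-a2 -1.29 (from 5.46) and Hbb-bt -0.74 (from 5.39). Newborn shares with all deposited barcodes were mixed 1.63% (from 0%) and endocrine 3.0% (from 9.80%). 1-week shares with all deposited barcodes were mixed 1.08% (from 0.0522%), monocyte 11.2% (from 12.9%) and endocrine 0.410% (from 2.56%). 3-week shares with all deposited barcodes were endocrine 0.196% (from 1.55%). 8-week shares with all deposited barcodes were endocrine 0.201% (from 1.04%). Medians with all deposited barcodes from newborn to 8-week were erythroid RNA 6.80 (from 5.61). 3-week shares with resolution 2 were mixed 6.61% (from 5.85%) and monocyte 3.19% (from 3.80%). Medians with resolution 2 from newborn to 8-week were interferon 0.22 (from 0.39) and inflammatory -0.55 (from -0.43).

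Medians with the mean of per-cell CPM from newborn to 8-week were MHC class II 6.15 (from 5.41), MHC class I 0.29 (from 0.38), border-associated -2.21 (from -2.71), microglia 0.43 (from 0.54), monocyte-derived -0.68 (from -0.91), interferon 0.20 (from 0.39), inflammatory -0.87 (from -0.43), immediate-early 0.063 (from 0.15), glycolysis -1.04 (from -1.17), oxidative phosphorylation -0.93 (from -1.10), hormone RNA 0.012 (from -0.47), erythroid RNA 5.45 (from 5.61) and B cell RNA 1.80 (from 0.15). Medians with the mean of per-cell CPM from newborn to 1-week were MHC class II 0.93 (from 0.58), MHC class I 0.036 (from 0.17), monocyte-derived -0.59 (from -0.19), cell cycle -0.58 (from -0.78), inflammatory 0.92 (from 1.20), immediate-early 0.91 (from 1.01), lysosome -0.036 (from 0.034), lipid handling -0.034 (from 0.33), scavenger 0.49 (from 0.32), growth factors 0.44 (from 0.67), transcription factors 0.37 (from 0.46) and hormone RNA 0.67 (from -0.10). Medians with the mean of per-cell CPM from 1-week to 3-week were MHC class II 4.09 (from 3.58), border-associated -3.00 (from -2.80), microglia 0.41 (from 0.51), monocyte-derived -0.017 (from -1.08), complement -0.50 (from -0.36), cell cycle -0.87 (from -0.63), interferon 1.41 (from 1.68), inflammatory -0.81 (from -0.66), immediate-early -0.75 (from -0.60), lysosome -0.27 (from -0.20), lipid handling -0.99 (from -0.91), hormone receptors 0.34 (from 0.49), growth factors 0.13 (from -0.25), transcription factors -0.20 (from -0.14), glycolysis -0.52 (from -0.65), hormone RNA 0.73 (from 0.12), neutrophil RNA -2.32 (from -3.13), B cell RNA 1.07 (from 0.56) and T and NK cell RNA 0.89 (from -0.57). Medians with the mean of per-cell CPM from 3-week to 8-week were MHC class II 0.73 (from 0.79), border-associated -0.10 (from -0.23), microglia 0.0069 (from -0.056), complement -0.045 (from -0.13), cell cycle -0.66 (from -0.89), interferon -0.23 (from -0.38), inflammatory -0.45 (from -0.54), lysosome 0.10 (from -0.014), purinergic signalling 0.045 (from -0.025), growth factors 0.12 (from -0.026), glycolysis -0.090 (from -0.15), oxidative phosphorylation -0.0072 (from -0.16), erythroid RNA -1.08 (from -1.32) and B cell RNA -1.0 (from -1.87). 1-week to 3-week log2 ratios of opposite sign with the mean of per-cell CPM were Cd3d 0.60 (from -2.17), Cd3g 0.53 (from -2.18), Plac8 0.051 (from -1.54) and S100a4 0.19 (from -2.58). 3-week to 8-week log2 ratios of opposite sign with the mean of per-cell CPM were Gzma -0.15 (from 1.04). Medians with a pseudocount of 5 CPM from newborn to 8-week were MHC class II 4.67 (from 5.41), border-associated -2.02 (from -2.71), cell cycle -1.76 (from -2.25), hormone RNA -0.080 (from -0.47) and erythroid RNA 3.87 (from 5.61). Medians with a minimum of 50 CPM from newborn to 8-week were border-associated -2.41 (from -2.71), immediate-early 0.12 (from 0.15), purinergic signalling 0.20 (from 0.57), glycolysis -1.62 (from -1.17), hormone RNA -0.89 (from -0.47) and B cell RNA -0.88 (from 0.15). Medians with no CPM minimum from newborn to 8-week were MHC class II 5.55 (from 5.41), MHC class I 0.89 (from 0.38), border-associated -2.19 (from -2.71), microglia 1.09 (from 0.54), monocyte-derived 0.17 (from -0.91), complement 0.35 (from -0.20), cell cycle -1.74 (from -2.25), interferon 0.95 (from 0.39), inflammatory 0.094 (from -0.43), immediate-early 0.67 (from 0.15), lysosome 0.39 (from -0.12), lipid handling 0.043 (from -0.35), scavenger 0.11 (from -0.33), hormone receptors 0.63 (from 1.0), growth factors -0.29 (from 0.046), glycolysis -0.66 (from -1.17), oxidative phosphorylation -0.59 (from -1.10), hormone RNA -1.84 (from -0.47), erythroid RNA 5.89 (from 5.61) and B cell RNA 1.13 (from 0.15).

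Medians with cells thinned to 1000 UMIs from newborn to 8-week were MHC class II 5.05 (from 5.41), MHC class I 0.62 (from 0.38), border-associated -2.11 (from -2.71), monocyte-derived -1.08 (from -0.91), complement -0.048 (from -0.20), cell cycle -1.89 (from -2.25), inflammatory -0.33 (from -0.43), lysosome -0.033 (from -0.12), lipid handling -0.15 (from -0.35), purinergic signalling 0.26 (from 0.57), growth factors -0.18 (from 0.046), transcription factors 0.11 (from 0.36), glycolysis -1.03 (from -1.17), oxidative phosphorylation -0.77 (from -1.10), erythroid RNA 1.77 (from 5.61) and B cell RNA -0.69 (from 0.15). Newborn to 8-week log2 ratios at the floor or under 10 CPM, of opposite sign but no direction, with cells thinned to 1000 UMIs were Ebf1 -1.89 (from 1.36), Nkg7 -0.62 (from 3.59) and P2ry14 -0.67 (from 1.49). Medians with cycling cells left out from newborn to 8-week were MHC class II 5.02 (from 5.41), monocyte-derived -0.78 (from -0.91), complement -0.36 (from -0.20), cell cycle -1.14 (from -2.25), inflammatory -0.58 (from -0.43), immediate-early 0.049 (from 0.15), lysosome -0.21 (from -0.12), lipid handling -0.52 (from -0.35), scavenger -0.58 (from -0.33), growth factors 0.67 (from 0.046), transcription factors 0.17 (from 0.36), glycolysis -1.29 (from -1.17), oxidative phosphorylation -1.0 (from -1.10), hormone RNA 0.80 (from -0.47) and B cell RNA 1.69 (from 0.15). Newborn to 8-week log2 ratios at the floor or under 10 CPM, of opposite sign but no direction, with cycling cells left out were Cga 1.97 (from -1.95), Cxcl1 2.77 (from -1.42), Hba-a1 -2.28 (from 5.91), Hba-a2 -2.28 (from 5.46) and Hbb-bt -1.66 (from 5.39). Medians with TMM scaling from 1-week to 3-week were T and NK cell RNA -1.81 (from -0.57). Genes also named with the filter on genes of other classes applied only in the library where the gene is higher numbered 6 of 24 from newborn to 8-week, 3 of 10 from newborn to 1-week and 4 of 10 from 1-week to 3-week.

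Genes also named with ranking by the ratio itself numbered 5 of 10 from newborn to 1-week. Markers with a lower share at 8-week with no thinning numbered 12 (from 6). Odds ratios with cells thinned to 2000 UMIs were Mrc1 with H2-Aa at 3-week 0.853 (from 0.592), Lyve1 with Cx3cr1 at 1-week 0.237 (from 0.467), Mrc1 with Cx3cr1 at newborn 1.62 (from 0.592), Mrc1 with P2ry12 at 1-week 1.13 (from 0.743), Cx3cr1 with P2ry12 at 1-week 2.31 (from 1.28) and Cx3cr1 with P2ry12 at 3-week 3.06 (from 1.97). Newborn to 8-week medians relative to random lists matched on expression and span (from those relative to all measured genes) were MHC class II 5.85 (from 5.41), MHC class I 1.0 (from 0.38), microglia 0.80 (from 0.54), monocyte-derived -0.51 (from -0.91), complement 0.18 (from -0.20), cell cycle -2.04 (from -2.25), interferon 0.90 (from 0.39), inflammatory 0.28 (from -0.43), immediate-early 0.81 (from 0.15), lysosome 0.10 (from -0.12), lipid handling -0.28 (from -0.35), scavenger -0.67 (from -0.33), hormone receptors 0.37 (from 1.0), growth factors 0.36 (from 0.046), transcription factors 0.24 (from 0.36), glycolysis -0.87 (from -1.17), oxidative phosphorylation -0.41 (from -1.10), hormone RNA 0.072 (from -0.47) and erythroid RNA 6.28 (from 5.61).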

Other observations

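The test of each explanation in this part was chosen before its result was seen, except the repeats with other seeds of the clustering. B lymphocytes make antibodies and mature from dividing precursors. In B cell-like cells, 436 at 1-week and 1046 at 8-week, cell cycle genes had a relative median of -3.82, with 18 of 18 members 2-fold lower at 8-week. The class held different clusters at these ages: 289 of the 1-week cells were in cluster 10 and 41 in the dividing cluster 14.4, and 890 of the 8-week cells in cluster 2. Medians of MHC class II and interferon response genes were higher, at 1.52 and 1.91, and those of glycolysis and oxidative phosphorylation genes lower, at -1.22 and -1.37. Genes that B cells should lack were higher too, with a median of 4.08 for hormone RNA (Gh and Prl alone) and 1.41 for complement, where C1qa, C1qb and C1qc were among 4 measured. RNA of other cells was not excluded as a source of the higher medians. Jchain, which joins antibody units, was 129.8-fold (interval 59.5 to 354) higher at 8-week. Vpreb2, part of the receptor of B cell precursors, had 0 UMIs at 8-week and was at least 140.3-fold lower. In T cell-like cells, 120 at 1-week and 948 at 8-week, the cell cycle median was -2.20, the interferon median 1.47 and the purinergic median 1.17. Here too the clusters differed, with 94 of the 1-week cells in cluster 15 and 458, 321 and 161 of the 8-week cells in clusters 22, 15 and 25. Their MHC class II median of 2.15 is of genes that T cells should lack, and RNA of other cells was not excluded as its source.

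Monocytes circulate and enter tissues in inflammation. In monocyte-like cells, 52 at newborn and 274 at 8-week, MHC class II genes had a relative median of 2.24, while interferon response and inflammatory genes had -1.23 and -1.06. Clusters 13 and 11 held 36 and 16 of these cells at newborn and 133 and 141 at 8-week. Genes of other classes were higher there too, with Gzma at 0 and 65.9 CPM, Cd79a at 1.51 and 32.4 CPM and Gh at 4.53 and 125 CPM. Neither the mix of clusters nor RNA of other cells was excluded as a source of the MHC class II difference. Neutrophil RNA had a median of -4.82. The survival gene Bcl2 was 12.7-fold (interval 7.53 to 23.3) higher at 8-week. The scavenger receptor gene Marco had 0 UMIs at 8-week and was at least 68.5-fold lower, and Apoc1 was 24.3-fold (interval 16.1 to 37.8) lower. In NK cell-like cells MHC class II genes had a median of 0.83 from 3-week to 8-week. NK cells should lack them too, as they should border-associated macrophage genes. Those had a median of -1.33, with Mrc1, Pf4 and Dab2 2-fold lower and Ms4a7 2-fold higher. In macrophage-like cells these medians had the same signs in this step, at -0.23 for border-associated and 0.79 for MHC class II genes. RNA of other cells was not tested as the source. In dendritic cell-like cells the chemokine Ccl17 was 3.37-fold (interval 2.44 to 4.77) higher at 8-week than at 3-week, and Fscn1, an actin bundler of migrating dendritic cells, 8.96-fold (interval 6.26 to 13.1) lower.

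Medians of oxidative phosphorylation and glycolysis genes were lower at 8-week than at newborn in macrophage-like cells, with 8 of 15 and 7 of 11 members at 2-fold. Gene length as the whole cause is argued against, since against random lists matched on expression and genomic span the higher of the 2 percentiles was 1.65. Relative to all measured genes the oxidative phosphorylation value was -1.10 and the glycolysis value -1.17. Relative to random lists matched on expression and span they were -0.41 and -0.87. These references differ in expression as well as span, so the part due to span alone was not measured. Gene length was thus not excluded for part of the difference. In monocyte-like cells the relative medians were -0.61 for oxidative phosphorylation and -0.62 for glycolysis. There 0 of 15 and 0 of 11 members were 2-fold lower. Both medians met the limit set beforehand for a difference between the libraries that reached more than 1 class. They were not matched on span, though, and ratios differed with span in monocyte-like cells too. These medians thus cannot separate span from a difference between the libraries. Such a difference and age, which the design names, are confounded here, and both stay open.

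Medians of immediate-early and inflammatory genes were higher at 1-week than at newborn in macrophage-like cells, with 4 of 16 and 7 of 14 members at 2-fold. A different mix of clusters as the whole cause is argued against for the cells tested. In 2 clusters made without these genes the relative medians ran from 0.769 to 1.26, over 72.8% of newborn and 54.7% of 1-week cells. With 10 other seeds the lowest and highest medians were 0.734 and 1.5. In the larger cluster, with 88 newborn and 286 1-week cells, they were 0.77 and 0.78. Over all macrophage-like cells they were 1.01 and 1.20, so a different mix was not excluded for part of the difference. The immediate-early median was -0.38 in monocyte-like and 0.93 in B cell-like cells. The inflammatory median was -0.82 and, from 5 measured genes, 0.71 in these classes. Both lists went opposite ways, so handling of the 1-week sample and age cannot be told apart.

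MHC class II genes were higher at 3-week than at 1-week also within clusters made without them, with relative medians from 3.36 to 3.60 in 3 clusters. These clusters held 23.9% of 1-week and 12.2% of 3-week macrophage-like cells, and the rest were not tested. With 10 other seeds, 3 to 4 clusters had enough cells, with medians from 0.39 to 5.45, and a median below 1 arose with 2 of the seeds. The clusters that carry this test thus depend on the seed, and a different mix of clusters stays open. Age stays open too, and it cannot be separated from a difference between the younger and older libraries. Border-associated genes had relative medians of -1.14, -0.98 and -2.68 in the same 3 clusters, against -2.80 in all macrophage-like cells, and from -2.68 to -0.59 with the other seeds, so a different mix was not excluded for part of that difference.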
